A study of Mus musculus with 2 samples.

How the data were processed

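Germ cells from adult C57BL/6 mouse testes were fixed with formaldehyde, sonicated and precipitated with an antibody against CREM or with goat IgG, per the labels' protocols. Cy5 marked the CREM precipitate and Cy3 the IgG precipitate on both arrays, per the labels, and the design text states that nothing was duplicated. Each array is a group of its own with 1 sample.

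Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.1.1 and probe positions refer to mouse build mm9 (NCBI build 37). The deposited scanner files give a spot's brightness as intensity in each channel, both as scanned, with a mean and a median local background, and as a processed signal that is background-subtracted and linearly dye-normalised. Per the file headers, the LogRatio column is log10 of processed Cy5 over Cy3. Other deposited columns are flags for spots that are saturated, not uniform, outliers or well above background, per the file headers. The authors' deposited value table holds log2 ratios whose scale, centring and direction were found by recomputing them. Subtracting the median background from the mean signal and applying limma's within-array loess returned them in the order of the scanner file, with a correlation of 1 and a largest difference of 5e-08 over 243464 spots of array 1, and 4.93e-08 over 243456 of array 2. Matched by feature number instead, they correlated with the processed ratio at only 0.104 and 0.0355. Their medians were -0.00096 and -0.00103. The submitters' processing notes name R 2.10.1 and limma.

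The main values were log2 of processed Cy5 over processed Cy3, centred on the median of the probes used (shifts of 0.02 on both arrays), with no loess, since most probes of a promoter array may carry signal. Control spots, outlier spots (46 and 9 probes), probes without a position (299 and 417) and probes not well above background in either channel (8573 and 10355) were left out, which left 228277 and 226404 probes. Saturated spots, 1 on each array, stayed in. The median processed signal was 751 for IgG and 753 for CREM on array 1, and 734 and 737 on array 2. Before dye normalisation, per the file headers, the median net signal was 34.7 in Cy3 and 125 in Cy5 on array 1, against a background noise of 2.97 and 3.53, and 29.8 and 105 on array 2, against 2.45 and 3.11.

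A window was 3 neighbouring probes with starts at most 500 bp apart, and its value the median. Windows at a log2 ratio of 1 or more (2-fold) were called, and those at -1 or less were counted as the background measured the same way. Called windows that share a probe formed a region. A gene's value was its highest window, a window belonging to the gene the array names for its middle probe. Of 17832 gene names in the files, 13983 were current symbols in a RefSeq table of assembly GRCm38.p6, used for names only, 2630 were updated through an unambiguous synonym and 1219 were kept. No genome sequence or mm9 annotation was used here, so exons and introns are not stated.

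For 19 gene lists, the median gene value was set among 10000 random lists drawn from genes of the same array and matched on the number of windows and mean brightness in 5 bins each. A list beyond the outer 2.5% on either side was taken as standing apart. The cAMP response element and its core, TGACG or CGTCA, were counted in probe sequences and compared with windows between -0.25 and 0.25 in the same stratum of GC content (bins of 4%) and CpG number (6 and more as 1 class), where it held at least 20 windows. Shares have 95% Wilson intervals, and shares of lists exact binomial ones, which cover counting error only. Negative distances to a start were read as upstream.

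The named genes were Crem, Creb1 and Atf1; per array, the 10 highest called genes and the 2 lowest genes whose window had all 3 probes well above background in both channels; and the 3 highest members of each list under the same filter. Not every gene this rule picks is named in the text. The lists, this rule, the thresholds and the other settings to be tried were fixed before the data were examined. These settings were normexp background correction (offset 50), within-array loess, the authors' values, the scanner's ratio uncentred, filters on dim and saturated spots, other window sizes, gaps, statistics and thresholds, mode centring, other matching and another gene value. Removal of the median ratio of each 2% GC bin (at least 50 probes), matching on GC and 1 window per region were added after seeing the data. A search of the sequence around windows was not run, as it needs a genome. Because no measured probe was repeated, the spread between duplicate spots came from control probes with at least 12 spots.

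The scripts were tested on simulated data with the real probe positions. The simulated values were the probe values without the GC trend, shuffled and each given a random sign, which breaks the correlation of neighbouring probes. Regions of 5 probes raised by a log2 ratio of 1 were found in 66.0% of 50 cases on array 1 and 80.0% on array 2, and those raised by 1.5 in 100% and 98.0%. Of 400 random lists of 30 genes, 5.75% and 5.00% lay beyond either tail. Values were computed with R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.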

Results

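Chromatin immunoprecipitation followed by hybridisation to promoter arrays was used to ask where CREM, a transcription factor of the CREB family that activates genes in haploid male germ cells, sat on the genome of adult mouse testis. Fixed germ cells from C57BL/6 testes were precipitated with an antibody against CREM, labelled with Cy5, or with goat IgG as the negative control, labelled with Cy3. The pair was hybridised to a set of 2 arrays that tile promoters. Array 1 covered chromosomes 1 to 8 and part of 9, and array 2 covered another part of 9, chromosomes 10 to 19 and X, with 117 windows on Y, 43 on chromosome 5, 25 on mitochondrial DNA and 14 on chromosome 1. The arrays shared 0 probes and each was hybridised 1 time, without a dye swap, so there were no replicates, no test across samples and no p-values. All ratios below are log2 of CREM over IgG, and dye and antibody cannot be separated in them. Of 237195 and 237185 probes on arrays 1 and 2, 96.3% and 95.5% were well above background in the CREM channel, and 77.4% and 78.5% in the IgG channel. The number of arrays limits the precision.

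Enrichment over IgG was found at promoters on both arrays. On array 1 the highest values under the rule for named genes lay at Larp7, which encodes a protein of a small nuclear ribonucleoprotein, at Sphk2, a sphingosine kinase, and at Rnf20, a ubiquitin ligase acting on histones. Larp7 had a log2 ratio of 3.61, the median of 3 probes between 1.59 and 4.52 (chromosome 3, 127256385 to 127256695, mm9). Sphk2 had 3.5 (probes 3.23 to 3.73; chromosome 7, 52972811 to 52973213) and Rnf20 had 3.36 (probes 2.12 to 3.41; chromosome 4, 49644131 to 49644703). Across 8 other settings Larp7 fell to 2.5 at the lowest, against 2.93 for Sphk2 and 3.2 for Rnf20. On array 2 the highest under this rule were BC051142 at 3.57 (probes 2.19 to 3.64; chromosome 17, 34535462 to 34535748), Oaz1, the antizyme of ornithine decarboxylase, at 3.5 (probes 2.67 to 4.32; chromosome 10, 80288734 to 80289127) and Ormdl3, a regulator of sphingolipid synthesis, at 3.36 (probes 2.20 to 3.44; chromosome 11, 98448665 to 98449074). Windows outside this rule reached 4.23 on array 1 and 4.16 on array 2.

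The other highest genes of array 1 were the spliceosome gene Snrpa (3.07), Vps37b (3.06), the ubiquitin-conjugating enzyme gene Ube2h (2.98), the tRNA nucleotidyltransferase gene Trnt1 (2.94), BC031781 (2.92), the helicase gene Dhx36 (2.85) and the actin regulator Wdr1 (2.82, or 1.54 with normexp background correction). The window at Dhx36 was the only one among the 20 highest genes under the rule for named genes whose probe sequences held a full CREM recognition sequence. On array 2 they were Pcnp (3.33), Zc3h10 (3.27), the ribosomal protein gene Rpl4 (3.18), the kinetochore gene Zwilch (3.18), the nuclear pore gene Nup153 (3.16), Snapc5 (3.16) and Cdadc1 (3.13). The windows of Rpl4 and Zwilch overlapped on chromosome 9, so they are a single enriched place, and Snapc5 lay on the same chromosome from 64026645. At Pcnp and Nup153 the probes disagreed, with the lowest of the 3 at -0.40 and -1.42.

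The gene of CREM itself and its relatives were lower. Crem had 0.63 in its highest window (probes 0.07 to 0.83; chromosome 18, 3332332 to 3332996) and was not called. Only 6 windows were named for Crem, against 19 for Creb1 and 7 for Atf1, so enrichment elsewhere in the gene may have gone unseen. Creb1 had 0.62 (probes 0.41 to 2.01; chromosome 1, 64577758 to 64578037), with IgG signal well above background at 1 of the 3 probes, and was not called either. Atf1 was called at 1.10 (probes 0.94 to 2.13; chromosome 15, 100057406 to 100058041), though across 8 other settings it ranged from 0.86 to 1.17.

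In all, 9950 of 175692 windows of 3 neighbouring probes on array 1 reached a log2 ratio of 1, and 8091 lay at or below -1, on the side of IgG. On array 2 the counts were 11028 and 7869 of 174595 windows. On array 1 the order turned with the authors' values (5186 and 5210) and with probes above background in both channels (5212 and 6348), and normexp background correction gave 2227 and 328. The CREM-side windows formed 3681 and 3992 regions, with median lengths of 687 and 694 bp, and named 2886 of 8655 genes on array 1 and 3080 of 8651 on array 2. IgG-side windows named 2980 and 2849 genes. The IgG side held the GC-rich windows, with a mean GC content of 58.8% and 58.1% against 40.9% and 41.1% on the CREM side. With the trend of the ratio along GC removed, an alternative chosen after seeing the data, IgG-side windows numbered 1807 and 2517 and CREM-side windows 8762 and 9897. Beyond a 4-fold ratio, 1046 windows lay on the CREM side and 474 on the IgG side of array 1, and 1312 and 714 on array 2. Probe values without the GC trend, shuffled and each given a random sign, gave 1756 and 2171 CREM-side and 1720 and 2153 IgG-side windows. Their like counts are those with the GC trend removed, where the IgG side held 1807 and 2517. Shuffling also breaks the correlation of neighbouring probes, so it gives no chance level for the windows.

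**Figure D1:**
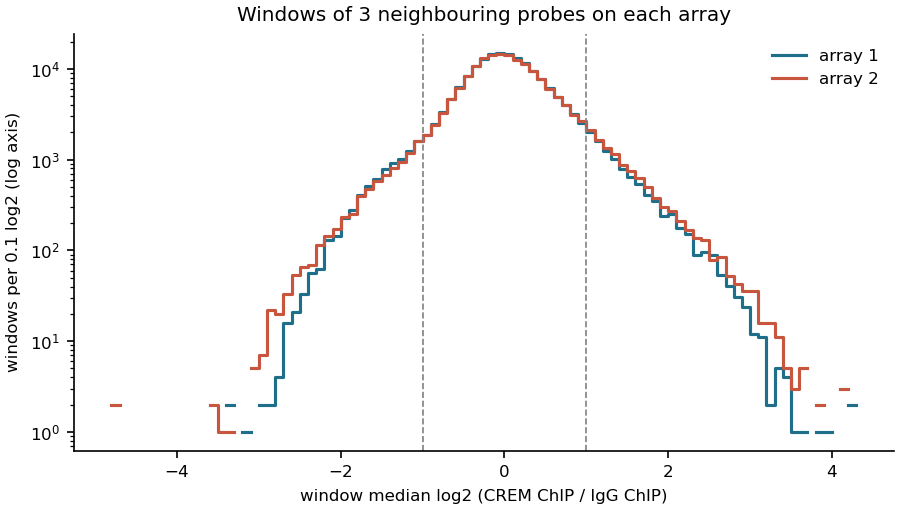
Number of windows of 3 neighbouring probes (log axis) by their median log2 ratio of CREM over IgG, for array 1 and array 2, with dashed lines at -1 and 1. Beyond 1 lie 9950 and 11028 windows and beyond -1 lie 8091 and 7869.

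Some windows lay far on the IgG side. Rnf151, on array 2, had -4.72 (probes -4.76 to 0.48; chromosome 17, 24852806 to 24853444), with a median signal of 20838 for IgG and 779 for CREM. Bmp4, a bone morphogenetic protein gene, had -3.56 (probes -3.72 to -3.47; chromosome 14, 47005370 to 47005695), and across 8 other settings it ranged from -3.56 to -2.10. On array 1, Proser2 had -3.38 (probes -3.43 to -3.11; chromosome 2, 6054233 to 6054801).

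Repeat measurements existed only for control spots, since 0 measured probes were spotted more than 1 time. The SD of the log2 ratio between spots of a control probe had a median of 0.27 over 14 control probes on array 1 (0.04 to 0.70) and 0.33 over 17 on array 2 (0.08 to 0.62). The closest pairs of probes correlated at 0.477 and 0.483 across probes, and the most distant pairs at 0.00619 and -0.0141. Probes are not independent replicates, and none of these values covers the spread between precipitations.

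Spermatid genes recalled as dependent on CREM stood above the rest. Of 25 measured genes recalled from earlier work as lowered in Crem knockout testis, 18 were called (72.0%, exact 95% interval 50.6 to 87.9%), against 34.5% of all 17303 genes. Their median of 1.28 exceeded 99.95% of 10000 random lists matched on window number and brightness. The members of lists named here had 3 probes well above background in both channels, and other members were higher in some lists. A call did not ask for this, and many called members had a dim probe in their highest window. Cyp51, which encodes an enzyme of sterol synthesis, had 2.60 (probes 0.62 to 2.90), or 1.41 with normexp background correction, Spata3 had 1.77 (1.18 to 1.83), which fell to 0.43 there, and the spermatid linker histone gene H1f7 had 1.64 (-0.35 to 2.19). Spermatid chromatin genes, 6 of which are also on the first list, were called at 13 of 19 (68.4%, 43.4 to 87.4%), with a median of 1.46 above 99.95% of random lists, or 94.1% in windows of 5 probes. The transition protein gene Tnp2 had 1.51 (0.33 to 1.74; chromosome 16, 10788891 to 10789226), or 0.88 with normexp, and Cdyl had 1.46 (1.05 to 1.90). The protamine genes Prm1 and Prm2, which are the usual examples of CREM targets and were picked out after their values were seen, reached 0.37 and 0.66 and were not called. At Prm1, 3 neighbouring probes lay at -2.64, -3.11 and -2.43, on the IgG side.

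**Figure D2:**
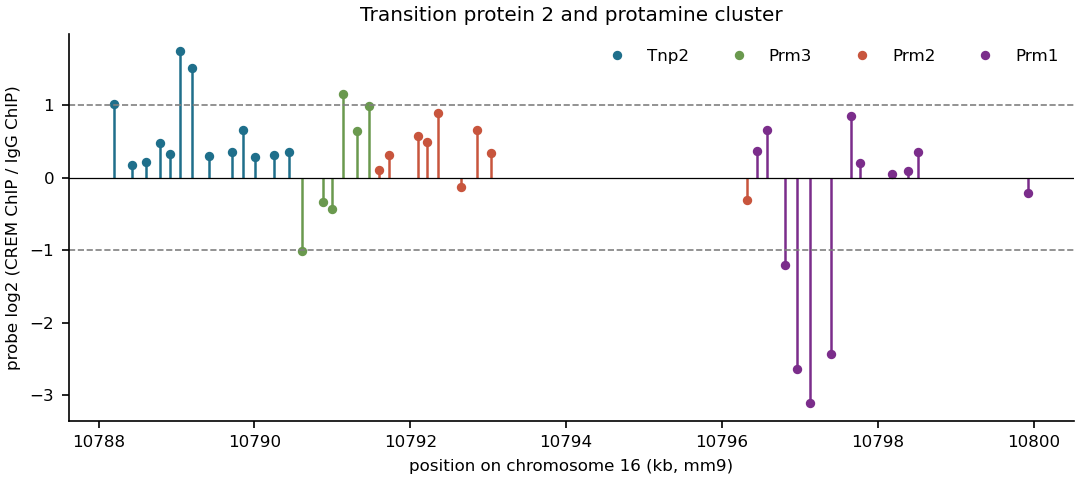
Log2 ratio of CREM over IgG for each probe along the cluster of Tnp2, Prm3, Prm2 and Prm1 on chromosome 16 (kb, mm9), coloured by the gene the array names, with dashed lines at -1 and 1. The highest probe, at 1.74, belongs to Tnp2 and the lowest, at -3.11, to Prm1.

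The cAMP-responsive targets of CREB proteins known from somatic cells were also high, with 19 of 31 called (61.3%, 42.2 to 78.2%) and a median of 1.20 above 99.72% of random lists, or 96.75% with normexp. Pcna, the replication clamp, had 2.63 (1.69 to 2.85), the circadian clock gene Per1 had 2.44 (1.61 to 2.5) and the immediate early gene Fosb had 2.44 with probes from -1.08 to 2.58, or 0.82 with normexp. Cholesterol synthesis genes were called at 15 of 24 (62.5%, 40.6 to 81.2%), and their median of 1.22 exceeded 99.52% of random lists. Idi1 had 2.77 (2.43 to 2.83) and Pmvk, a kinase of the mevalonate pathway, had 2.56 (2.30 to 2.80). Cyp51 is on this list as well as on that of the Crem knockout.

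Genes of other lists from spermatogenesis did not pass the upper tail in the main setting. Meiotic prophase genes were called at 14 of 29, with a median of 0.96 above 94.22% of random lists and from 34.8% to 98.81% across 15 other settings, and Mael had 1.76 and Msh5 1.61. Sperm tail and axoneme genes were called at 16 of 29 (median 1.03, above 97.21%), with Spag6 at 1.84 (1.13 with normexp), Ropn1 at 1.74 (1.04 with normexp) and Dnaic1 at 1.69. This list did pass the tail with loess (98.63%), with the authors' values (98.4%) and with the mean of all probes (99.94%), among others. Acrosome and sperm surface genes were called at 9 of 22 (0.86, above 77.42%), with Acrbp at 2.20, Adam1a at 1.02 and Calr3 at 0.96, and passed the tail with normexp (99.51%) and with the mean of all probes (99.78%). Spermatogonial genes were called at 7 of 24 (0.73, above 18.85%), with Bcl6b at 2.63, Foxo1 at 1.06 and Etv5 at 0.83. A window at or below -1 was found at 16 of these 24 genes (66.7%), at 15 of 26 neuronal genes (57.7%) and at 13 of 31 cAMP-responsive targets (41.9%), against 33.7% of all genes, and a gene can have windows on both sides. The share was lower at sperm tail (13.8%), acrosome (13.6%), olfactory receptor (10.6%) and keratin genes (6.94%), among others. These shares were not matched on window number or GC content.

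Liver, skeletal muscle, olfactory receptor and keratin genes lay in the lower tail, and Leydig and neuronal genes did so in fewer settings. Sertoli cell markers were called at 5 of 19 (median 0.63, above 7.78% of random lists, inside the tails), with Trf at 0.73, Fabp3 at 0.67 and Cldn11 at 0.63. Leydig cell and steroid synthesis genes were called at 3 of 15 (0.51, above 1.94%), with Insl3 at 1.09, Hsd17b3 at 0.51 and Star at 0.23. Its other called members, Fdx1 at 2.05 and Fdxr at 1.43, were picked out after their values were seen and had a probe not well above background in a channel. None of 24 liver genes was called, which allows a share of up to 14.2%, and their median of 0.42 exceeded 0.04% of random lists, with Ambp at 0.65, F10 at 0.57 and Tat at 0.45. Skeletal muscle genes were called at 1 of 24 (0.49, above 0.09%, or 11.26% with normexp), with Tnni2 at 0.60, Mb at 0.48 and Acta1 at 0.40. Neuronal genes were called at 6 of 26 (0.63, above 1.64%), with Snap25 at 1.58 (0.87 with normexp), Syn1 at 1.41 and Dlg4 at 1.18. Olfactory receptor genes were called at 149 of 795 and keratin genes at 8 of 72, with medians of 0.55 and 0.41 that exceeded 0% of random lists. The highest members whose 3 probes were well above background in both channels were Olfr215 at 2.15, Olfr181 at 1.02, Olfr735 at 0.94, Krt6a at 0.94, Krt222 at 0.93 and Krtap14 at 0.77. Among called olfactory receptor genes only Olfr215 and Olfr181 passed this filter in their highest window, and no called keratin gene or Sertoli marker did. The Leydig list kept its place in the lower tail in 5 of 15 other settings and the neuronal list in 6, and both turned with normexp, where they exceeded 53.2% and 56.8% of random lists.

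Among genes used in every cell, 3 of 4 lists passed the upper tail in the main setting. Ribosomal protein genes were called at 36 of 79 (median 0.99, above 99.38% of random lists), with Rpl4 at 3.18, Rpl24 at 2.81 and Rps9 at 2.46 (1.55 with normexp), but fell inside the tails with normexp (94.64%), the mean of 3 probes (94.39%) and windows of 5 (96.52%). Spliceosome genes were called at 28 of 53 (1.05, above 99.76%, or 94.3% with the mean of 3 probes), with Snrpa at 3.07, Prpf38b at 2.34 (1.25 with normexp) and U2af1l4 at 2.11 (1.28 with normexp). Oxidative phosphorylation genes were called at 33 of 77 (0.89, above 98.8%, kept beyond the tail in 8 of 15 other settings), with Atp5d at 2.93, Uqcrfs1 at 2.43 and Ndufa10 at 2.21, all of which had a probe below 0. Proteasome genes were called at 16 of 37 (0.94, above 95.99%, inside the tails, but 97.8 to 99.48% in 5 of 15 other settings), with Psmb2 at 1.67, Psmb6 at 1.64 and Psmb1 at 1.51 (0.86 with normexp). Adam1a, Foxo1, Insl3, Dlg4 and Olfr181, all called here, fell below 1 in at least 1 other setting, to 0.88, 0.36, 0.39, 0.59 and 0.72 at the lowest. The intervals given with list counts cover the sampling of genes only, and a list percentile describes these arrays.

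**Figure D3:**
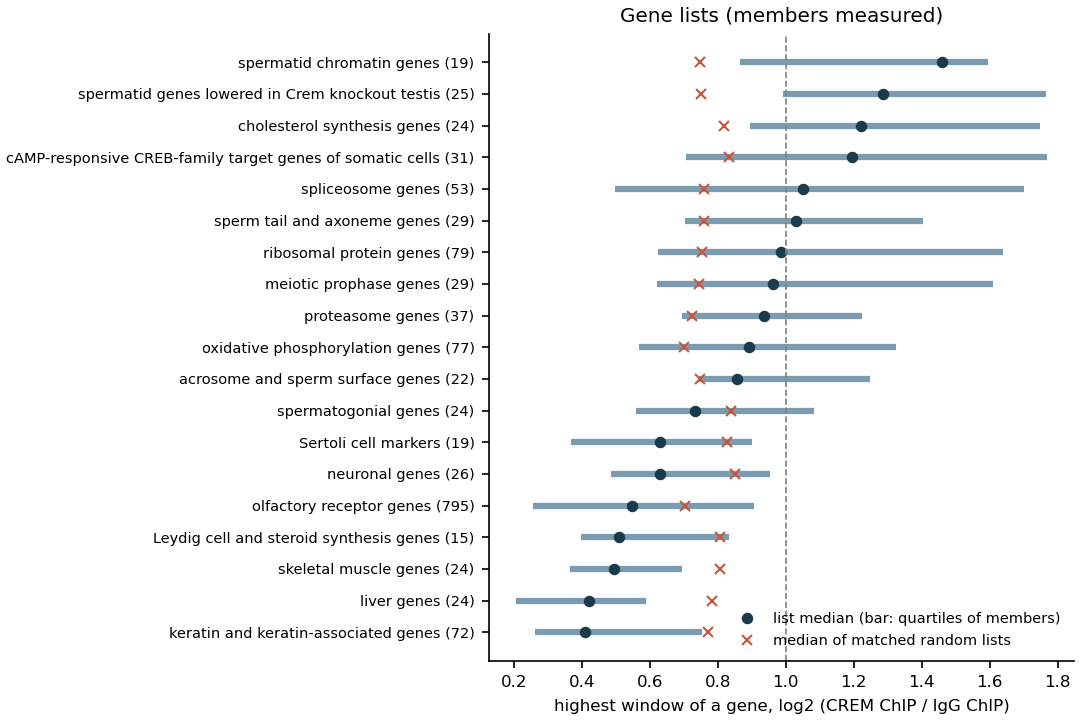
Median over each gene list of the highest window per gene (dots, log2 ratio of CREM over IgG), with bars between the quartiles of the members, crosses for the median of matched random lists and a dashed line at 1; members measured stand in brackets. Spermatid chromatin genes lie highest at 1.46 and keratin genes lowest at 0.41.

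CREM binds the cAMP response element, TGACGTCA, and its core, TGACG or CGTCA, and their frequency was lowest in windows near 0 and rose towards either side. On array 1 the full element stood in the probe sequences of 0.136% of windows between -0.25 and 0.25 (95% Wilson interval 0.111 to 0.166%), 0.431% of those from 1 to 1.5 (0.300 to 0.619%), 1.01% from 1.5 to 2 (0.667 to 1.52%) and 2.20% from 2 upwards (1.47 to 3.28%). On array 2 the shares were 0.0965% (0.0759 to 0.123%), 0.490% (0.353 to 0.681%), 0.891% (0.595 to 1.33%) and 1.91% (1.29 to 2.80%). Neighbouring windows share probes, so these intervals are too narrow. The core rose from 5.28% to 18.8% on array 1 and from 5.39% to 18.1% on array 2. Windows at or below -1, which were GC-rich, held the full element at 0.655% (0.501 to 0.856%) and 0.267% (0.175 to 0.408%) and the core at 14.7% and 13.4%. Against unchanged windows matched on GC and CpG content, called windows held the full element 3.60 times as often on array 1 and 5.57 times as often on array 2, and the core 1.32 and 1.30 times as often. With 1 window per region, chosen after seeing the data, the full element stood in 22 of 3674 matched windows on array 1 and 19 of 3983 on array 2, or 3.11 and 3.87 times the matched shares. On the IgG side, where 6012 of 8091 and 7013 of 7869 windows could be matched, the full element stood at 0.595 and 0.330 times the matched shares and the core at 0.962 and 0.977 times. With 1 window per region the interval of the full element on array 1 (0.452 to 1.16%) took in the matched 1.04%, so a difference was not detectable there. Only probe sequences were searched, so an element between probes went unseen.

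**Figure D4:**
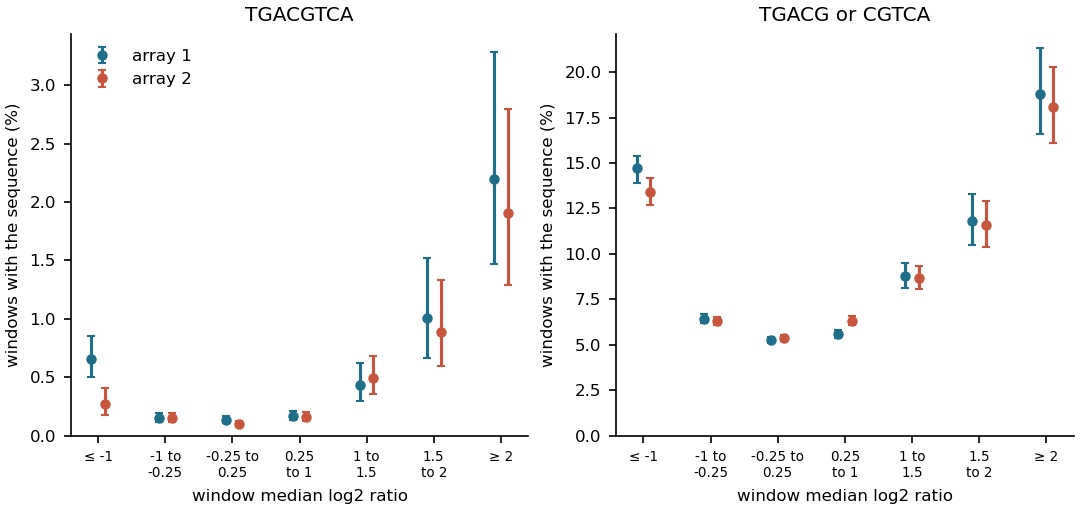
Percent of windows whose probe sequences hold the full cAMP response element (left) or its core, TGACG or CGTCA (right), by window median log2 ratio, for array 1 and array 2, with 95% Wilson intervals. The full element rises from 0.136% and 0.0965% in windows between -0.25 and 0.25 to 2.20% and 1.91% from 2 upwards, and stands at 0.655% and 0.267% at or below -1.

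Enrichment flanked those transcript starts to which the array design gives a distance. Only 10982 probes had one, of 228277 used on array 1 and 226404 on array 2, so other promoters are not covered. For 1021 transcripts the array design gives each probe's distance to the start, and 15.3% of probes lying 200 to 500 bp upstream reached a ratio of 1 (95% Wilson interval 12.7 to 18.3%), against 7.72% within 200 bp of the start (6.22 to 9.56%). From 200 to 500 bp downstream the share was 12.7% (10 to 16%), and in the bin from -5500 to -4000 bp it was 6.44% (5.26 to 7.85%). Per array, the upstream share was 14.0% and 16.3% and that at the start 8.12% and 7.41%. Within 200 bp of the start, 16.2% of probes lay at or below -1. Neighbouring probes are not independent, so the intervals given here are too narrow. The X chromosome held called windows at 8.18% and the autosomes of array 2 at 6.19%, but the order turned with the authors' values (2.25% and 2.79%), with normexp (1.84% and 3.72%) and with probes above background in both channels (4.30% and 4.87%).

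**Figure D5:**
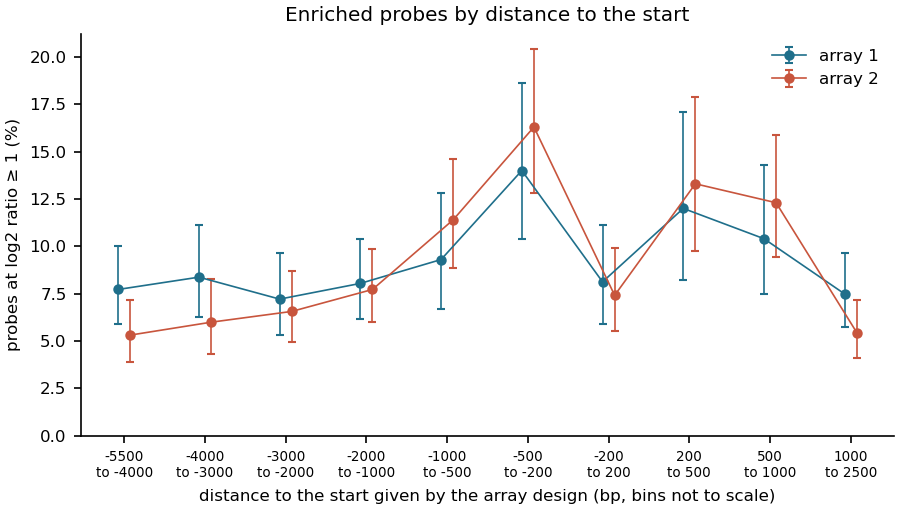
Percent of probes at a log2 ratio of 1 or more by distance to the transcript start given by the array design (bp, bins not to scale), for array 1 and array 2, with 95% Wilson intervals. Only the 10982 probes with such a distance are covered. The share peaks 200 to 500 bp upstream, at 14.0% and 16.3%, and is 8.12% and 7.41% within 200 bp of the start.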

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

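Removal of the GC trend, matching on GC and the use of 1 window per region were chosen only after the data were seen; the other alternatives were planned. Across 15 alternatives the lists of Crem knockout, cholesterol synthesis, liver, olfactory receptor and keratin genes stayed beyond the same tail, with the Crem knockout list between 99.86% and 100% of random lists. Called windows held the full cAMP response element at 2.40 to 6.43 times the matched share on array 1 and 3.80 to 8.52 times on array 2. Of 80 named genes, 56 moved by more than the median control SD with normexp, 27 with the authors' values, 4 without the GC trend and 1 with loess, and none that was called changed sign in the settings run. The pairs below are arrays 1 and 2, and where no reason is given the cause was not tested. The search of the sequence around windows was not run. Signal over background limits the IgG channel most, since fewer probes were well above background there.

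Enriched windows, IgG-side windows, enriched regions and enriched genes numbered, with normexp, 2227 and 6286, 328 and 862, 960 and 2343, and 881 and 1921. With the authors' values they were 5186 and 4802, 5210 and 4249, 1815 and 1657, and 1535 and 1424. In windows of 5 probes they were 6326 and 7070, 4767 and 4702, 1680 and 1873, and 1584 and 1752. A threshold of 1.5-fold gave 25427 and 26562, 21296 and 20835, 8799 and 9008, and 5523 and 5621. A log2 ratio of 1.5 gave 3226 and 3892, 2529 and 2653, 1269 and 1511, and 1113 and 1331. A threshold of 3 robust SDs gave 3564 and 4068, 2884 and 2785, 1392 and 1576, and 1207 and 1382. With both channels above background, which leaves fewer probes, enriched windows numbered 5212 and 6047, regions 2008 and 2238, and genes 1689 and 1865. IgG-side windows numbered 6348 and 6016, against 8091 and 7869 in the main setting. Enriched windows, 9950 and 11028 there, fell further, so the smaller number of probes does not by itself account for their fall. The dimmest of 8 equal groups of probes had median log2 ratios of 0.434 and 0.412, and the other groups 0.0251 at most. With the GC trend removed, IgG-side windows numbered 1807 and 2517. The CREM side held 55.2% and 58.4% of calls in the main setting, 87.2% and 87.9% with normexp, 82.9% and 79.7% without the GC trend, and 45.1% and 50.1% with both channels above background. The normexp offset of 50 was added before any dye normalisation. It exceeds the median net signal of Cy3, 34.7 and 29.8, but not that of Cy5, 125 and 105. Such an offset compresses ratios, so the smaller counts and the changed split with normexp may come from it.

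The share of called windows with the full element and with its core, TGACG or CGTCA, was 1.17% and 13.7% on array 1 with normexp, where the core stood at 12% on array 2. The full element stood at 1.35% and 1.23% with the authors' values, 1.12% and 1.08% with both channels above background, 0.425% and 0.452% at 1.5-fold, 1.40% and 1.23% at a log2 ratio of 1.5, 1.41% and 1.21% at 3 robust SDs and 1.02% and 0.941% without the GC trend. The core stood at 13.2% and 14.1%, 11.5% and 12.6%, 7.92% and 8.48%, 14.1% and 13.8%, 13.9% and 13.6%, and 12% and 11.8% in the same order. With 1 window per region array 2 had 0.477% and 9.74%.

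Percentiles among random lists moved across a tail as follows. With normexp they were 96.75 for cAMP-responsive, 99.51 for acrosome, 53.2 for Leydig, 11.26 for muscle, 56.77 for neuronal, 94.64 for ribosomal and 87.84 for oxidative phosphorylation genes. With loess, sperm tail genes stood at 98.63, Leydig at 3.72, neuronal at 2.79, proteasome at 97.8 and oxidative phosphorylation at 96.92. The authors' values gave 98.4, 6.61, 10.34 and 98.48 for sperm tail, Leydig, neuronal and proteasome genes, and both channels above background gave 99.5, 2.74, 35.66 and 99.41. Mode centring gave 3.03 for Leydig and 2.71 for neuronal genes. The mean of 3 probes gave 98.81 for meiotic, 4.78 for neuronal, 94.39 for ribosomal and 94.3 for spliceosome genes. Windows of 5 probes gave 98.03 for sperm tail, 94.1 for spermatid chromatin, 1.78 for Sertoli, 17.22 for Leydig, 5.33 for neuronal, 96.52 for ribosomal and 89.45 for oxidative phosphorylation genes. Starts at most 300 bp apart gave 98.93 for sperm tail, 4.24 for Leydig, 98.12 for proteasome and 83.56 for oxidative phosphorylation genes. Matching on size only gave 97.54 for sperm tail, 4.67 for Leydig, 13.06 for neuronal and 93.8 for oxidative phosphorylation genes. The mean of all probes gave 99.78 for acrosome, 99.94 for sperm tail, 37.96 for Leydig, 6.38 for neuronal and 99.48 for proteasome genes. Without the GC trend, sperm tail genes stood at 99.15, Leydig at 11.52 and oxidative phosphorylation at 93.49, and matched on GC the last stood at 96.61.

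Near starts, the share of enriched probes within 200 bp and 200 to 500 bp upstream was 3.76% and 6.61% with normexp, 3.66% and 7.56% with the authors' values, and 4.70% and 10.5% with both channels above background. The X chromosome differed from autosomes by -1.88, -0.539 and -0.566 percentage points in these settings, and by 1.25 with loess, 0.870 with no filter on dim probes and 1.26 without the GC trend, against 1.99.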

Other observations

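The ranking of 8-mers, the listing of IgG-side regions and the tests of GC content and dye brightness were chosen after the results were seen, while the test of CRE cores at genes used in every cell was chosen before.

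With the GC trend removed, 6 regions of array 1 and 22 of array 2 lay at or below -2. Apart from Rnf151 at -4.39, Proser2 at -3.53 and Bmp4 at -3.50, and picked out after their values were seen, they took in Med16 at -3.48, Stra8, a gene of the entry into meiosis, at -2.74 (chromosome 6, 34870259 to 34871103, mm9), and Prm1 at -2.73 (chromosome 16, 10796781 to 10797685). The regions at Stra8, Prm1, Rnf151 and Proser2 spanned 845, 905, 990 and 993 bp. Mitochondrial DNA lay on the same side, with all 25 of its windows between -2.73 and -2.18 before the GC trend was removed. All 14 windows of array 2 on chromosome 1, at 24620110 to 24622907, lay between -2.65 and -2.18. With the GC trend removed, this stretch and mitochondrial DNA had like values, -2.75 and -2.82, and like mean log2 brightness, 13.9 and 13.4. Whether they are separate signals was not tested. Whether amplified DNA in the IgG sample raised the IgG signal of the regions at Rnf151, Proser2, Bmp4, Stra8 and Prm1 was not tested, and it would lower the ratios given for them.

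Among all 8-mers found in at least 100 probes, ranked by the mean log2 ratio of their probes relative to probes of like GC and CpG content, TGACGTCA ranked 3 of 22955 on array 1 (0.345 over 144 probes) and 8 of 23033 on array 2 (0.292 over 115 probes). The first and second on array 1 were ATGACGTC and GACGTCAC, which share 7 of their bases with it, and they ranked 19 and 9 on array 2. Of the others that ranked 4 to 10 on array 1, ACGTCACT, ACGTCACA, TGACGTAA, ACGTCATC and AACGTCAC ranked 94, 14, 784, 280 and 15069 on array 2, and CGGAGGGA and TCCGAAAA ranked 44 and 83.

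Many windows lay on the IgG side, and they were GC-rich. A dye bias that follows spot brightness is weakly argued against, since loess on the processed signals lowered their number by at most 1.08%. The authors' values, made with loess after another background subtraction, held 5210 and 4249 of them, against 8091 and 7869 in the main setting. Their CREM-side windows also fell, from 9950 and 11028 to 5186 and 4802. Which step gave these falls was not tested. Whether this side grew with GC content in the absence of CpG could not be decided. Among separate windows whose probes hold no CpG, 1 of 257 at 50% GC or more and 0.34% under 45% GC lay at or below -1 on array 1. On array 2 they were 2 of 264 and 0.68%. The ratios were 1.15 and 1.12, with too few windows at high GC. Removing the GC trend lowered the number by 77.7% and 68.0%, which does not bear on the cause, since the trend came from the same probes. Among the windows of 50% GC or more without CpG, the upper 95% Wilson bounds of the share were 2.17% and 2.72%. Both lie below the IgG-side share of all windows, 4.6% and 4.5%. This argues against a GC content of 50% or more, without CpG, as enough to give this side. GC content and CpG number were not separated in windows that hold CpG. Dye and antibody were never swapped, and no biological explanation was tested.

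Fewer probes were enriched at the start site than beside it. GC content of the probes is weakly argued against as the whole cause. Among probes under 45% GC the share within 200 bp was 10.8% (95% Wilson interval 8.50 to 13.7%). It was 18.7% (15.4 to 22.5%) 200 to 500 bp upstream, a difference of -7.85 percentage points. Neighbouring probes are not independent, so these intervals are too narrow, and the GC content of the sequence around the probes was not tested. On array 1 alone the intervals overlapped, at 13.5% (9.63 to 18.6%) and 17.7% (12.9 to 23.9%). Other technical causes may remain, and no biological explanation was tested.

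Ribosomal protein, spliceosome and oxidative phosphorylation genes, which are used in every cell, stood high beside spermatid genes. GC content is only weakly argued against for spliceosome and ribosomal protein genes, since without the GC trend these lists stood at 99.44 and 99.46 among random lists. This test is weak, since the trend came from the same probes and higher GC content went with lower ratios (r of -0.426 and -0.389). GC content stays open for oxidative phosphorylation genes, which fell from 98.8 to 93.49, with a median of 0.89 and then 0.78. This list also left the tail in settings that do not touch GC, with 83.56 for starts at most 300 bp apart and 89.45 for windows of 5 probes. A pull-down of open promoters without CREM could not be excluded: the CRE core, TGACG or CGTCA, stood in 15.9% of the highest windows of 113 called genes of these lists and the proteasome list (10.3 to 23.8%), against 10.6% in matched windows, so the interval takes in the matched share. Whether CREM or accessible chromatin gave this enrichment cannot be told apart here, and a precipitation from Crem knockout testis would bear on it. A pull-down of open promoters without CREM was not tested for the spermatid lists and stays open for them too.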
